A study of Homo sapiens with 4 samples.

How the data were processed

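Total RNA of U87 glioblastoma cells was sequenced after depletion of ribosomal RNA. Per the labels' protocols, cells were seeded, kept for 24 h, given fresh medium with 50 mM carnosine or without it, and extracted after another 24 h. Stranded total RNA libraries were pooled, 4 in all, and read as pairs of 101 bases on a single flow cell. No sequencing batch that parts the groups is given.

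The authors deposited a table of raw counts per gene, whole numbers with no normalization, with an Ensembl identifier and a symbol in each row. Per the submitters' processing notes, bcl2fastq 2.17.0, HISAT2 2.1.0 and HTSeq 0.6.1 were used with the genome build hg38. The annotation release, the treatment of reads with several matches and the strand setting are not given in the sources used here. Reads that match several places can be left out or shared by such a pipeline, which bears on gene families, pseudogenes and regions with more than 1 copy in the reference. In the deposited counts, 39 of 710 genes whose exonic bases lie entirely under exons of the opposite strand had a mean count of at least 10, with a highest mean of 2505. These counts can be the genes' own and do not show reads of the wrong strand. Because the strand setting is not given, counts of overlapping and antisense genes remain uncertain. Column names of the table equal the sample titles, and 0 columns of other samples were present.

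Gene types and coordinates were taken from GENCODE 29 (GRCh38) by identifier without version. Of 58219 genes in the table, 57881 matched, 55008 of them with the same version, and 338 did not. GENCODE 29 also lists transcripts outside the primary assembly, on patches and alternate loci, for the symbols of 2028 genes.

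Genes were kept by edgeR's filterByExpr with its defaults (a minimum count of 10, or 0.171 CPM at the median library size, in 2 libraries, and a total of 15). This left 16340 genes and removed 41879, of which 32116 had no count. The tested genes held at least 99.96% of each library's counts. Libraries were scaled by TMM factors of 0.991 and 0.992 for the controls and 1.04 and 0.976 for the carnosine libraries. The comparison used edgeR 4.0.16 (quasi-likelihood F test, two-sided, group as the only term, 2 residual degrees of freedom) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, in R 4.3.3. CPM values use the scaled library sizes. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic and is approximate. The common biological coefficient of variation was 0.141 and the prior degrees of freedom were 4.92. Smallest adjusted p values were 0.00336.

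Gene lists, 41 with 680 genes, were fixed before the data were examined, as were the groups, the tests, the other settings and the rule for named genes. All 680 genes were found in the table. The 38 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. Of these, 9 passed, 4 up and 5 down. With an estimated correlation 0 passed, and 0 had an unadjusted p under 0.05. With fry 0 passed, and 7 had an unadjusted p under 0.05. The counts called adjusted over the list alone use Benjamini-Hochberg adjustment of edgeR p values within a list.

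The rule named the 12 largest rises and 12 largest falls among genes past the threshold with a mean count of at least 100, libraries of the groups apart and a symbol that is not a clone name. It also named up to 4 passing members of each list, or 2 with the most counts where none passed, and a set of 15 genes around carnosine, glucose use and growth. Of that set, 1 gene is not reported here. XIST and Y-linked genes were left out. CITED2, DDIT3, BNIP3, PIK3R1, COL1A2, RRP12, SNHG15, SNHG5 and the DNA replication genes other than CDC45, RFC3, CCNE1 and CCNE2 lie outside the rule and were named after their values were seen.

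Replicates are separate samples in the labels, which do not say that they came from separate cultures. The p values then measure the spread between these samples, which may be technical. Replicates were not copies of a library: the chi-square of their counts was 33.8 times its degrees of freedom for the controls and 53 times for carnosine.

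The tests were tried on a single set of simulated counts for the same 16340 genes, drawn with dispersions that edgeR estimated. In it 200 genes outside the lists were changed, and the DNA replication list was shifted by -0.6. The edgeR test recovered 19.4% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 84.8% of those changed 4-fold, and 10 of its 132 calls (7.58%) were false. DESeq2 made 163 calls, 29 of them (17.8%) false, and limma-voom 131 calls, 9 of them false. Camera with the preset correlation called the shifted list and 0 others. Genes were drawn independently, so simulated lists lacked the correlation estimated in the data, such as 0.277 for DNA replication and 0.721 for mitosis. The simulation therefore does not test the preset of 0.01.

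Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, a test against a fold of 1.5, the replicate number as a block, removal of mitochondrial and the 20 most counted genes, and each library left out, which leaves 1 library against 2 and 1 residual degree of freedom. Removal of genes also listed outside the primary assembly was added after the data were seen. Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6 was used for further checks.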

Results

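U87 is an established human glioblastoma line, and carnosine is the dipeptide beta-alanyl-L-histidine. The comparison asks which transcripts of these cells differ when 50 mM carnosine is present in the medium. There were 2 libraries from cells kept for 24 h with carnosine and 2 from cells kept for the same time without it. Gene counts summed to 71766267 and 59155538 in control replicates 1 and 2, and to 57728762 and 51632970 in carnosine replicates 1 and 2. Between 21763 and 22271 genes had at least 1 count in a library. RN7SL2, an RNA of the signal recognition particle, took the most counts in each library, from 3.13% in control replicate 1 to 4.92% in carnosine replicate 2. Log2 values of counts scaled by library size (CPM) correlated across 16340 genes with r = 0.9902 between the controls and r = 0.9881 between the carnosine libraries, against a median of 0.9811 between libraries of different groups. These correlations are across genes, which are not independent replicates.

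Carnosine raised RANBP3L, a binding partner of SMAD proteins, 20.1-fold (log2 fold change 4.33 ± 0.27 SE, n = 2 each), and lowered EIF5, a translation initiation factor, 3.82-fold (-1.93 ± 0.11). GRIN2A, a subunit of the NMDA receptor, rose 5.75-fold (2.52 ± 0.18), PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, 5.25-fold (2.39 ± 0.21), and ARG2, the mitochondrial arginase, 4.97-fold (2.31 ± 0.14). NOP56, a core protein of box C/D snoRNA particles, was 3.28-fold lower, and SAT1, the acetyltransferase of polyamine breakdown, 3.35-fold lower. Of 16340 genes tested, 1358 (8.31%) changed at an adjusted p under 0.05, 645 higher and 713 lower. Among these, 259 were more than 2-fold higher and 106 more than 2-fold lower. Protein-coding genes made up 555 of the higher and 663 of the lower genes. Both carnosine libraries lay beyond both controls, on the same side, for 9239 (56.5%) of all genes tested, where chance gives 33.3% on average. Genes are not independent and no spread of that share was estimated, so the excess is not a test. The count fell to 635 without control replicate 1 and to 505 without control replicate 2, of which 536 and 445 were among the 1358. With 1 library left out, 1 residual degree of freedom remains and the spread within a group comes from the other group alone, so a call lost or gained there can come from the smaller design rather than from that library. The count was 23 in a test against a fold of 1.5.

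**Figure D1:**
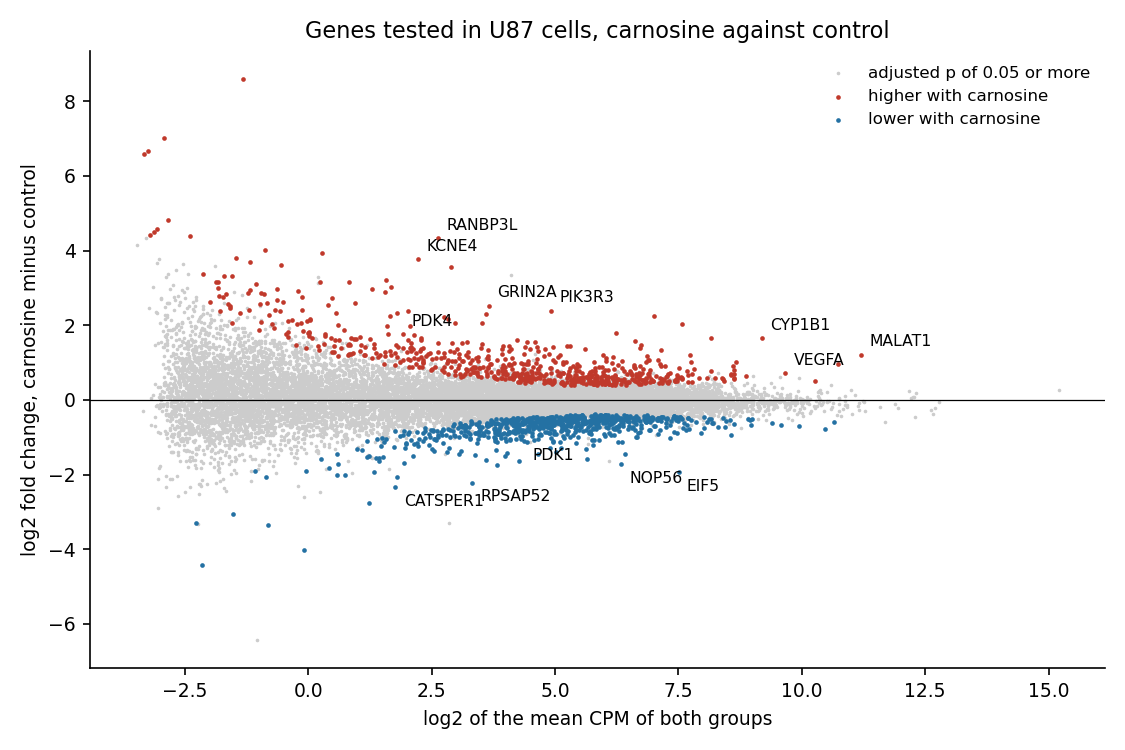
Each point is 1 of the tested genes (XIST and Y-linked genes are not drawn), with the log2 of its mean CPM over both groups on the x axis and the log2 fold change of carnosine against control (n = 2 each) on the y axis. The 645 genes that were higher are red, the 713 that were lower are blue, and a selection of the named genes is labelled, with RANBP3L at 4.33 and EIF5 at -1.93.

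Among the 12 largest rises, RANBP3L (ENSG00000164188.8, chromosome 5, 36248434 to 36302114, GRCh38) went from 0.579 ± 0.216 CPM in controls to 11.8 ± 1.13 CPM with carnosine (SD, n = 2 each), a log2 fold change of 4.33 ± 0.27 (SE, adjusted p = 0.00336, edgeR's quasi-likelihood test). KCNE4, a potassium channel subunit, had a log2 fold change of 3.77 ± 0.39 (adjusted p = 0.0108), which was 4.53 without control replicate 1. LBH, a transcriptional cofactor of the Wnt pathway, had 3.55 ± 0.75 (adjusted p = 0.0373), with 5.34 and 22.0 CPM in the 2 carnosine libraries and an adjusted p of 0.0852 in limma-voom. The log2 fold change of LBH was 2.94 and 4.52 without control replicates 1 and 2, and 4.24 and 2.19 without carnosine replicates 1 and 2. ZDHHC11, GALNT15, HIF1A-AS1, NFE2 and ZNF295-AS1 rose by log2 fold changes of 3.21, 2.97, 2.61, 2.38 and 2.33. HIF1A-AS1 had 3.40 without control replicate 2. HIF1A-AS1, ZNF295-AS1 and ARG2 share exonic bases with genes of the opposite strand, and the strand setting of the counting is not given in the sources used here. PARN, the poly(A)-specific ribonuclease, had a log2 fold change of 2.90 ± 0.66 (adjusted p = 0.0440), but its counts of 85 and 10 in the controls and 291 and 284 with carnosine lie in a stretch of chromosome 16 with few counts, and DESeq2 gave an adjusted p of 0.0757. Its log2 fold change was 4.92 without control replicate 1 and 2.13 without control replicate 2.

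Among the 12 largest falls, EIF5 (ENSG00000100664.10, chromosome 14, 103333544 to 103345025, GRCh38) went from 287.8 ± 6.97 CPM to 75.4 ± 6.47 CPM (SD, n = 2 each), a log2 fold change of -1.93 ± 0.11 (SE, adjusted p = 0.00336). NOP56 fell by 1.72 ± 0.10 on the log2 scale (adjusted p = 0.00336) and SAT1 fell by 1.74 ± 0.20 (adjusted p = 0.0113). CATSPER1, a sperm calcium channel, UCN2, the peptide urocortin 2, and NECAB2 had log2 fold changes of -2.33, -2.07 and -2.02. ADCY7, an adenylate cyclase, and PAPPA2, a protease of insulin-like growth factor binding proteins, had -1.70 and -1.63. The noncoding SP2-AS1 had -1.65, and the pseudogenes MEMO1P1, RPSAP52 and FAM86JP had -2.76, -2.21 and -1.92. These pseudogenes resemble other genes in sequence, so their counts depend on how reads with several matches were treated. MEMO1P1 had -2.03 and -4.12 without carnosine replicates 1 and 2. Exons of ADCY7 also lie under exons of the opposite strand.

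Of 22 tested DNA replication genes, 15 fell and 0 rose, and all 22 log2 fold changes lay below 0, with a median of -0.61. CDC45 and RFC3, a helicase cofactor and a clamp loader subunit, fell by 0.99 ± 0.11 and 0.94 ± 0.09 (SE; adjusted p = 0.0113 and 0.00939), and the cyclins CCNE2 and CCNE1 by 0.91 ± 0.15 and 0.89 ± 0.15. With p adjusted over the list alone, 19 members fell. The set test, camera with a preset correlation, gave an adjusted p of 1.25e-13, and the adjusted p was 0.79 with an estimated correlation. The calls of MCM2, MCM3, MCM5, MCM6, PCNA and CDC6 ended without control replicate 1 (adjusted p from 0.0677 for CDC6 to 0.204 for MCM6) and without control replicate 2 (0.0731 for MCM2 to 0.162 for MCM5), while their log2 fold changes stayed between -0.45 and -0.61 and between -0.53 and -0.68. The calls of CDT1 (0.135) and MCM7 (0.0645) ended without control replicate 1, those of CCNE1 (0.0564) and ORC1 (0.0638) without control replicate 2, MCM5 also without carnosine replicate 1 (0.0769) and MCM6 also without carnosine replicate 2 (0.0520).

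Of 22 mitosis genes 2 fell, HMMR by 0.76 ± 0.13 and CDC20 by 0.59 ± 0.13 on the log2 scale, and the median was -0.18. The list had a camera adjusted p of 0.0101, 0.825 with an estimated correlation, 0.146 without control replicate 1 and 0.316 without carnosine replicate 1. There were 3 falls adjusted over the list alone. CDC20 was not called without control replicate 1 (adjusted p = 0.176), control replicate 2 (0.0781) or carnosine replicate 1 (0.0700). Of 15 replication-dependent histone genes, 0 passed the edgeR test, over all genes or adjusted over the list alone, with 6 at an unadjusted p under 0.05, 5 past the DESeq2 test and 0 past limma-voom. All 15 log2 fold changes lay below 0 with TMM scaling and 14 with each of 3 other scalings, where HIST1H1E did not, and the median was -0.40. That list had a camera adjusted p of 0.00543, 0.825 with an estimated correlation and 0.303 without carnosine replicate 1. HIST1H1C and HIST1H1E, the members with the most counts, had log2 fold changes of -0.06 and -0.002. The proliferation marker MKI67 had -0.52 ± 0.23 (adjusted p = 0.204) and the cell cycle inhibitor CDKN1A -0.03 ± 0.13 (adjusted p = 0.910), and neither passed.

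Of 21 tested ribosome biogenesis genes and MYC targets, 5 fell and 0 rose, with a median log2 fold change of -0.44. Besides NOP56, these were BOP1 at -0.77 ± 0.11, RRS1 at -0.55 ± 0.10, NCL, or nucleolin, at -0.51 ± 0.11, and RRP12 at -0.44 ± 0.10. There were 16 falls adjusted over the list alone. Camera gave an adjusted p of 3.56e-08, and the adjusted p was 0.79 with an estimated correlation. The calls of RRS1, NCL and RRP12 ended without control replicate 1 (adjusted p = 0.0802, 0.157 and 0.202) and without control replicate 2 (0.110, 0.234 and 0.169), and those of NCL and RRP12 without carnosine replicate 1 (0.0672 and 0.119). MYC itself had a log2 fold change of -0.44 ± 0.17 and did not pass (adjusted p = 0.142).

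**Figure D2:**
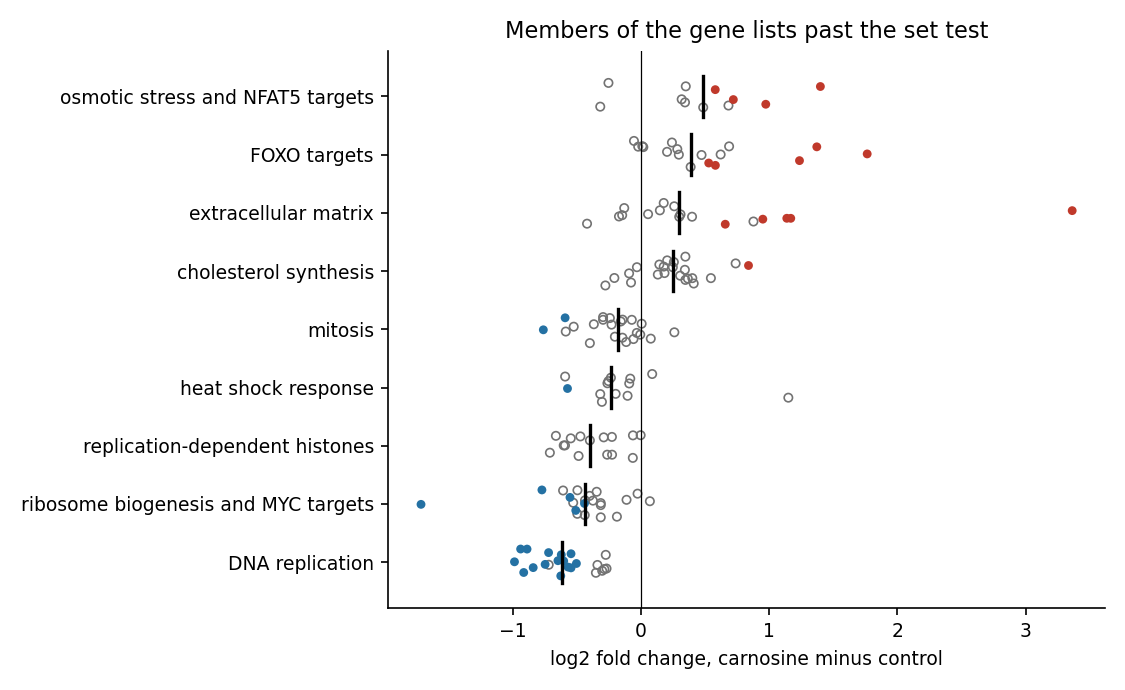
Each point is a tested member of 1 of the 9 gene lists past camera with a preset correlation (0 passed with an estimated correlation and 0 with fry), with its log2 fold change of carnosine against control (n = 2 each) on the x axis. Filled points passed the gene test (red higher, blue lower), open points did not, and the vertical bars are list medians, from -0.61 for DNA replication to 0.49 for osmotic stress; points are spread vertically only to separate them.

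Of 17 tested targets of FOXO transcription factors, 5 rose, 12 did not pass and the median log2 fold change was 0.39. Camera gave an adjusted p of 1.61e-04, and the adjusted p was 0.79 with an estimated correlation. PDK4, the kinase that switches off pyruvate dehydrogenase, went from 1.71 ± 0.25 CPM to 5.83 ± 0.58 CPM (SD, n = 2 each), 3.40-fold higher (log2 fold change 1.76 ± 0.22 SE, adjusted p = 0.0123). FBXO32, the ubiquitin ligase atrogin-1, rose 2.59-fold, SESN3, a sestrin, 2.36-fold, and TXNIP and CITED2 by 0.58 ± 0.12 and 0.53 ± 0.10 on the log2 scale. TXNIP inhibits thioredoxin and glucose uptake. Adjusted over the list alone, 8 rose and 0 fell. The calls of SESN3, TXNIP and CITED2 ended without control replicate 1 (adjusted p = 0.118, 0.167 and 0.119) and without control replicate 2 (0.129, 0.121 and 0.161), and that of SESN3 without carnosine replicate 2 (0.0885).

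Of 11 tested osmotic stress genes and targets of NFAT5, the transcription factor of hypertonic stress, 4 rose and 7 did not pass. S100A4 was 2.64-fold higher, AKR1B1, the aldose reductase that makes sorbitol, 1.96-fold, SLC5A3, a myo-inositol transporter, 1.65-fold, and SLC38A2, an amino acid transporter, 1.49-fold. There were 5 rises adjusted over the list alone. The median log2 fold change was 0.49, and camera gave an adjusted p of 0.00928, 0.79 with an estimated correlation. The call of AKR1B1 ended without control replicate 2 (adjusted p = 0.169), that of SLC5A3 without control replicate 1 (0.0646), and that of SLC38A2 without control replicate 1 (0.167), control replicate 2 (0.178) and carnosine replicate 2 (0.0632).

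Of 17 tested extracellular matrix genes, 5 rose and 12 did not pass. THBS1, or thrombospondin 1, rose 2.25-fold from 16.9 ± 1.45 to 38.0 ± 0.40 CPM (SD, n = 2 each), LUM, the proteoglycan lumican, 2.20-fold, and the fibrillar collagen COL5A2 1.93-fold. COL1A2 rose by 0.66 ± 0.15 on the log2 scale. COL3A1 passed with a log2 fold change of 3.36 ± 0.65, from 2 and 3 counts in the controls to 23 and 23 with carnosine. There were 8 rises and 1 fall adjusted over the list alone. The median was 0.30, and camera gave an adjusted p of 0.00543, 0.79 with an estimated correlation. Without any 1 of the 4 libraries COL3A1 was not called (adjusted p from 0.0642 to 0.153), LUM was not called without control replicate 1 (0.0812), and COL1A2 was not called without control replicate 2 (0.243) or carnosine replicate 1 (0.0580).

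Cholesterol synthesis genes had a median log2 fold change of 0.25, and 17 of 22 lay above 0. INSIG1, which holds back sterol regulatory element-binding proteins, was the member that rose, 1.79-fold, and adjusted over the list alone no member passed. Camera gave an adjusted p of 0.0101, 0.825 with an estimated correlation and 0.183 without control replicate 2. INSIG1 was not called without control replicate 2 (adjusted p = 0.119) or carnosine replicate 1 (0.0628). Of 13 heat shock genes, HSP90AA1 fell by 0.58 ± 0.13 on the log2 scale, and 2 fell adjusted over the list alone. The median was -0.23, and camera gave an adjusted p of 0.0449, which became 0.79 with an estimated correlation, 0.175 without control replicate 2, 0.0718 without carnosine replicate 1 and 0.05 with genes of a mean count of at least 10. HSP90AA1 was not called without control replicate 1 (0.22) or control replicate 2 (0.172). HSPA1A and HSPA1B, inducible members of that list, lie in a block of chromosome 6 with almost no counts in any library and were not tested.

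Genes of glucose use went both ways. PDK1, a second kinase of pyruvate dehydrogenase, fell by 1.11 ± 0.17 on the log2 scale (2.15-fold lower, adjusted p = 0.0182) while PDK4 rose, and 11 of the 13 tested genes of pyruvate dehydrogenase control did not pass. Adjusted over the list alone, 4 rose and 1 fell. In glycolysis the hexokinase HK2 rose 1.59-fold and the glucose transporter SLC2A1 1.46-fold, while the enolase ENO2 was 1.61-fold and the phosphofructokinase PFKL 1.45-fold lower, with 16 of 20 members not past the test. Adjusted over the list alone, 2 rose and 3 fell. Among 21 hypoxia genes, VEGFA (1.65-fold), BHLHE40 (1.62-fold) and SLC2A1 rose and PDK1 and BNIP3 fell, and adjusted over the list alone 4 rose and 5 fell. HIF1A had a log2 fold change of 0.62 ± 0.16 (adjusted p = 0.0610) and VHL 0.14 ± 0.10 (adjusted p = 0.403), and neither passed. The camera adjusted p was 0.217 for pyruvate dehydrogenase control, 0.673 for glycolysis and 0.796 for hypoxia. The camera direction of glycolysis and hypoxia turned from down to up without carnosine replicate 1 (adjusted p = 0.719 and 0.549), and that of hypoxia also without control replicate 2 (0.781). The calls of HK2, SLC2A1, PFKL, VEGFA, BHLHE40 and BNIP3 ended without either 1 of the controls (adjusted p from 0.0679 to 0.217), that of ENO2 without control replicate 1 (0.113), SLC2A1 also without carnosine replicate 2 (0.0603), and BNIP3 also without carnosine replicate 1 (0.0876) or 2 (0.0593).

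**Figure D3:**
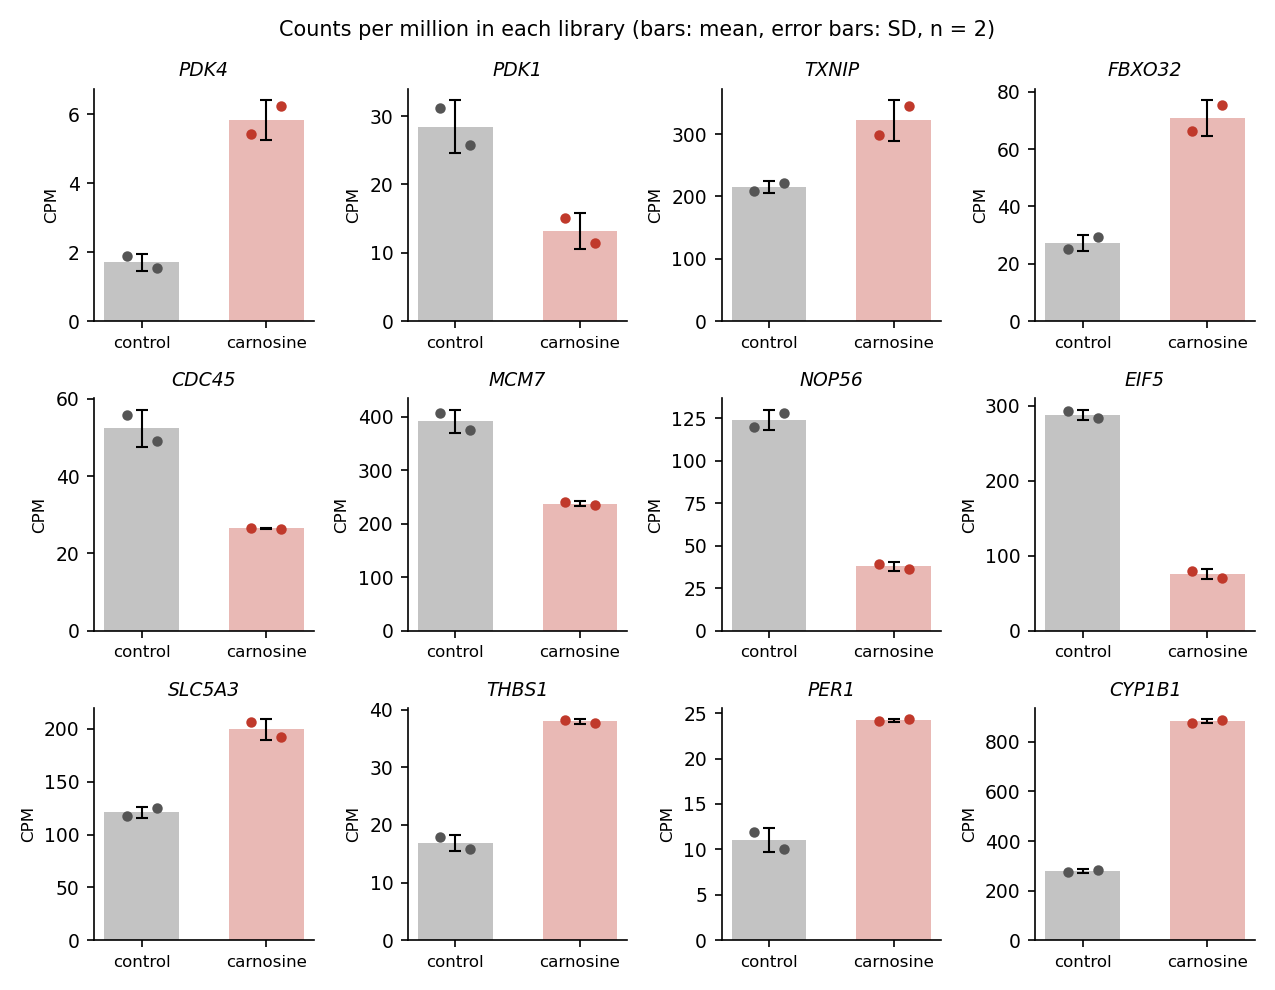
Points are the CPM of each library, bars the group means and error bars the SD (n = 2 each), with a linear y axis from 0 in each panel. PDK4 rose from a mean of 1.71 to 5.83 CPM, NOP56 went from 124.2 to 37.8 CPM, and in each of the 12 genes both carnosine points lie outside the control points.

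Over all genes and adjusted over the list alone, edgeR called 0 of 20 genes of the citric acid cycle and nuclear oxidative phosphorylation, 0 of 13 mitochondrially encoded mRNAs and 0 of 8 tested genes of carnosine and histidine handling. At an unadjusted p under 0.05 there were 4, 1 and 5, DESeq2 and limma-voom called 0 of each, and the camera adjusted p was 0.796, 0.263 and 0.428. Without control replicate 2 the mitochondrial mRNAs were called down (camera adjusted p = 0.0262), and the direction of the first list turned from down to up (0.905), as it did without carnosine replicate 1 (0.567). CNDP2, the cytosolic dipeptidase that can cleave carnosine, had a log2 fold change of -0.27 ± 0.09 (adjusted p = 0.109), and the peptide and histidine transporter SLC15A4 had -0.32 ± 0.12 (adjusted p = 0.139). HARS, the histidyl-tRNA synthetase, had -0.24 ± 0.10 (adjusted p = 0.154). CARNS1, the carnosine synthase, had 1 count in carnosine replicate 2 and none elsewhere. ATP5B had -0.01 (0.007 with upper-quartile scaling and 0.015 with total counts only), SDHA 0.31, MT-CO1 -0.07 and MT-CO3 -0.24. TALDO1 of the pentose phosphate pathway fell by 0.44 ± 0.10, the 1 of 9 members to pass over all genes or adjusted over the list alone, and its call ended without any 1 of the 4 libraries (adjusted p from 0.0570 to 0.240). PDK4 was the 1 of 17 fatty acid oxidation genes and PPAR targets to rise, with 1 up and 1 down adjusted over the list alone. Camera gave adjusted p values of 0.0551 and 0.263 for these lists. The pentose phosphate list was called down without control replicate 2 (0.0191), without carnosine replicate 2 (0.0448), with total counts only (0.0488) and with no filter on low counts (0.00805).

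Amino acid stress genes and ATF4 targets held 4 falls and 1 rise among 23. SLC7A11, the cystine transporter, was 2.21-fold lower, SHMT2 1.74-fold and PHGDH, of serine synthesis, 1.70-fold, DDIT3 fell by 0.71 ± 0.16, and STC2, a secreted glycoprotein, was 2.55-fold higher. Adjusted over the list alone, 2 rose and 9 fell. The camera adjusted p was 0.114, and the list was called down without control replicate 1 (1.34e-04), without carnosine replicate 1 (0.0107) and with no filter on low counts (0.00691). HSPA5, the chaperone BiP, was 1.59-fold lower and the 1 of 17 unfolded protein response genes to pass, with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.0650, but 0.0337 without control replicate 1, 0.00925 without carnosine replicate 2 and 0.00715 with no filter). Among 20 NRF2 targets and antioxidants, AKR1C1 (4.13-fold) and AKR1C3 (1.62-fold) rose, while SLC7A11 and GCLM fell, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.307, but 0.0231, down, without carnosine replicate 1). AKR1C1 and AKR1C3 are close in sequence, so reads can be shared between them, and AKR1C1 had a log2 fold change of 2.68 without control replicate 1 against 2.05 with all libraries. MT1E was 1.97-fold lower, the 1 of 14 metal handling genes to pass, with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.617, down, and 0.997, up, without carnosine replicate 1). Without either 1 of the controls the calls of PHGDH, HSPA5 and GCLM ended (adjusted p from 0.0739 to 0.108). The calls of SHMT2 (0.0663), DDIT3 (0.162) and AKR1C3 (0.144) ended without control replicate 2, DDIT3 (0.0649) and GCLM (0.0570) without carnosine replicate 2, and AKR1C3 (0.0676) without carnosine replicate 1.

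In signalling, the platelet-derived growth factor receptors PDGFRA and PDGFRB rose 3.07-fold and 1.80-fold, the kinase regulators TSC1 and PIK3R1 by 0.49 ± 0.10 and 0.48 ± 0.10 on the log2 scale, and EIF4EBP1, the translation repressor that mTOR phosphorylates, was 1.78-fold lower. These were 4 rises and 1 fall among 25 components of PI3K, AKT and mTOR signalling, with 5 up and 1 down adjusted over the list alone and a camera adjusted p of 0.263. EGFR had a log2 fold change of 0.08 ± 0.12 and did not pass (adjusted p = 0.723). EGR2 rose 2.74-fold, and SPRY4 and FOSL1 were 1.94-fold and 1.65-fold lower among 19 immediate early and MAPK feedback genes, with 1 up and 3 down adjusted over the list alone (camera adjusted p = 0.307, but 0.0115, down, without carnosine replicate 2). TGFB2 rose 2.50-fold and AMOTL2 1.51-fold, while LTBP2, a matrix protein of microfibrils, fell by 1.58 ± 0.10 on the log2 scale and ID1 by 0.77 ± 0.12, the 4 of 19 TGF-beta and YAP targets to pass over all genes or adjusted over the list alone (camera adjusted p = 0.796, down, and 0.997, up, without carnosine replicate 1). PDGFRA had an adjusted p of 0.0557 in limma-voom, and a log2 fold change of 0.98 without carnosine replicate 2 against 1.62 with all libraries. The calls of TSC1 and PIK3R1 ended without either 1 of the controls (adjusted p from 0.130 to 0.195), PIK3R1 also without carnosine replicate 1 (0.0599), FOSL1 (0.152) and ID1 (0.0668) without control replicate 1, and AMOTL2 (0.210) without control replicate 2.

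The chemokine CCL2 rose by 3.17 ± 0.38 on the log2 scale, from 0.347 ± 0.106 to 3.18 ± 1.01 CPM (SD, n = 2 each), the 1 of 17 inflammatory genes to pass over all genes or adjusted over the list alone (camera adjusted p = 0.263, but 0.0142, up, without carnosine replicate 1). Of 17 interferon response genes, IFIT1, IFIT3 and IFIH1 rose 2.16-fold, 1.85-fold and 1.58-fold and IFI44 was 1.55-fold lower, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.206). BMF, a pro-apoptotic BCL2 family member, rose 3.96-fold and CASP8 was 1.56-fold lower among 16 apoptosis regulators, with 2 up and 4 down adjusted over the list alone (camera adjusted p = 0.989). BMF had a log2 fold change of 1.39 without carnosine replicate 1 against 1.98 with all libraries. The camera direction of the apoptosis list was down while its median of 0.08 and mean of 0.10 lay above 0. It was up without control replicate 2 (camera adjusted p = 0.937), without carnosine replicate 2 (0.924) and with genes of a mean count of at least 10 (0.987). FDXR was 1.82-fold lower, the 1 of 21 p53 targets to pass over all genes or adjusted over the list alone (camera adjusted p = 0.617). HDAC5 and HDAC8 rose and HDAC9 fell among 20 histone deacetylases and acetyltransferases, with 2 up and 4 down adjusted over the list alone (camera adjusted p = 0.836, down, but up without control replicate 1 at 0.629 and without carnosine replicate 2 at 0.924). Without control replicate 2 the calls of IFIT1, IFIH1, IFI44, CASP8, HDAC5, HDAC8 and HDAC9 ended (adjusted p from 0.0984 to 0.230), and those of IFIH1, HDAC5, HDAC8 and HDAC9 also without control replicate 1 (0.118 to 0.163). Without carnosine replicate 1 those of IFIT1, IFIH1, HDAC8 and HDAC9 ended (0.0621 to 0.0801), and without carnosine replicate 2 those of IFIH1, IFI44, HDAC5 and HDAC9 (0.0624 to 0.0738).

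In lipid and lysosome genes, LPIN1 and GPAM rose 1.65-fold and 1.51-fold among 13 fatty acid synthesis genes, with 3 up adjusted over the list alone (camera adjusted p = 0.406, but 0.038 without control replicate 1). GPNMB rose 1.41-fold, the 1 of 21 autophagy and lysosome genes to pass, with 3 up adjusted over the list alone (camera adjusted p = 0.217). TXNIP was the 1 of 7 genes of glucose sensing and MondoA targets to rise, with 2 up adjusted over the list alone (camera adjusted p = 0.272). Of 15 genes of matrix proteases and invasion, edgeR called 0 over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.543, up, and 0.897, down, without carnosine replicate 2), where MMP2 and CD44 had log2 fold changes of 0.20 and 0.25. GPNMB was not called without any 1 of the 4 libraries (adjusted p from 0.0596 to 0.289), GPAM was not called without control replicate 1 (0.0854), control replicate 2 (0.159) or carnosine replicate 2 (0.0580), LPIN1 without control replicate 2 (0.0660), and TXNIP without control replicate 1 (0.167) or 2 (0.121).

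The nuclear noncoding RNAs NEAT1, LINC-PINT, MALAT1 and KCNQ1OT1 rose 3.14-fold, 2.37-fold, 2.32-fold and 2.23-fold. MALAT1 and NEAT1 together took 0.166% and 0.143% of the counts in controls and 0.427% and 0.329% with carnosine. SNHG15 and SNHG5, hosts of small nucleolar RNAs, fell by 0.67 ± 0.14 and 0.39 ± 0.09 on the log2 scale. Of 12 tested members of this list 4 rose and 2 fell, 4 and 5 adjusted over the list alone, and the camera adjusted p was 0.673. Of 9 tested abundant short noncoding RNAs, edgeR, DESeq2 and limma-voom called 0, as did edgeR adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.796), among them RN7SL2 at 0.27 and SNORD3A at 0.07. The list has 15 members, and those with few or no counts, such as RN7SK and RN7SL1 with 0 in each library, were not tested. Without carnosine replicate 1 this list was called up (camera adjusted p = 0.00704), and its direction turned to down without carnosine replicate 2 (0.122) and without control replicate 1 (0.93). The calls of SNHG15 and SNHG5 ended without control replicate 1 (adjusted p = 0.0591 and 0.203), control replicate 2 (0.151 and 0.232) and carnosine replicate 1 (0.0777 and 0.0995), and that of SNHG5 without carnosine replicate 2 (0.0692).

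Among 10 astrocyte and glioma markers, SLC1A3, a glutamate transporter, rose by 1.07 ± 0.17 on the log2 scale and CHI3L1 by 0.56 ± 0.10, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.217, but 0.0401, up, without carnosine replicate 1). Of 5 neuron and 6 epithelial markers edgeR called 0, with 1 up and 3 down, and 0, adjusted over the list alone (camera adjusted p = 0.325 and 0.796). At an unadjusted p under 0.05 there were 4 and 2, DESeq2 called 2 and 0, and limma-voom 0 of each. The camera direction of the epithelial list was down, but up without control replicate 1 (adjusted p = 0.848) and without carnosine replicate 2 (0.924). TUBB3 and SNAP25 had log2 fold changes of -0.42 and -0.67, and KRT8 and MUC1 -0.48 and 0.80. CNP was the 1 oligodendrocyte marker tested, at 0.07 (adjusted p = 0.695), and did not pass over all genes or adjusted over the list alone. CSF1R, a macrophage growth factor receptor, was 2.67-fold lower and 1 of 2 tested leukocyte markers, and PECAM1, an endothelial adhesion molecule, rose 2.42-fold and was 1 of 2 tested endothelial and erythroid markers, the same counts as adjusted over each list alone. Lists with fewer than 5 tested members had no set test. CHI3L1 was not called without control replicate 1 (adjusted p = 0.129) or 2 (0.119), nor PECAM1 without control replicate 1 (0.0582). The reference transcripts GAPDH and ACTB had log2 fold changes of -0.06 ± 0.16 and -0.26 ± 0.16 and did not pass (adjusted p = 0.844 and 0.356).

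Among the genes named here, 16 lost their call when libraries were scaled by total counts alone, with adjusted p from 0.0503 to 0.0793. These were AKR1B1, AKR1C3, BNIP3, CASP8, DDIT3, ENO2, FOSL1, GCLM, HDAC9, IFI44, IFIT1, INSIG1, PARN, PHGDH, SLC7A11 and SNHG5. In limma-voom IFI44 and SNHG5 had adjusted p values of 0.0557 and 0.0511. With upper-quartile scaling DDIT3, HDAC9, IFI44, PHGDH and SNHG5 had 0.0511 to 0.0564, and PHGDH had 0.0515 with the size factors of DESeq2.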

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

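All 1358 changed genes that were tested kept their sign in each alternative, and 1282 or more kept their call in DESeq2, limma-voom, other scalings than total counts (1082), and without a filter. DESeq2 called 2008 genes (932 higher, 1076 lower), more than edgeR each way. It made more false calls on a single set of simulated counts, drawn with dispersions that edgeR estimated. No filter gave 3145 genes (1514 higher, 1631 lower), and a test against a fold of 1.5 gave 23 (15 higher, 8 lower), a stricter null by construction. Leaving out 1 library gave 505 to 1595 genes, 235 to 729 higher and 270 to 866 lower, lowest without control replicate 2 and highest without carnosine replicate 2, each with 1 library against 2 and the spread from the other group alone. The set test called 9 lists, 8 to 12 with other scalings, filters or libraries, 0 with an estimated correlation and 0 with fry. With the replicate number as a block, which leaves 1 residual degree of freedom, 5767 genes passed (2771 higher, 2996 lower) and 12 lists. Among these lists were amino acid stress (camera adjusted p = 4.25e-05), nuclear long noncoding RNAs (0.00404) and astrocyte markers (0.0291). The labels do not say that the numbers pair the samples, and 2 pairs are too few to settle it. Across genes, the differences between replicates 1 and 2 correlated with r = 0.31 between control and carnosine. Libraries of the same number thus shared part of their difference, and the main test has no term for it. Groups of 2 give too few splits of the libraries to reach a share under 0.05. The edgeR test called 1358 genes in the real split and 0 in the others. Those others put 1 control and 1 carnosine library in each group. The carnosine difference then adds to the spread, so few calls could arise and the 0 is no support. At an unadjusted p under 0.05 there were 640 genes for replicates 1 against replicates 2 and 30 for the crossed split. Without genes also listed outside the primary assembly 1374 genes passed, of which 1335 were among the 1358. Values of uncalled genes near 0 changed sign: ATP5B 0.007 with upper-quartile scaling and 0.015 with total counts, and HIST1H1E 0.000 in DESeq2, 0.005 with its size factors, 0.014 with upper-quartile scaling, 0.014 with total counts and 0.001 at a mean count of at least 10. With 1 library left out the ranges were ATP5B -0.076 to 0.050, MT-CO1 -0.160 to 0.017, HIST1H1C -0.365 to 0.181, HIST1H1E -0.314 to 0.249, RN7SL2 -0.103 to 0.556, SNORD3A -0.229 to 0.308, EGFR -0.006 to 0.158, GAPDH -0.214 to 0.071 and CDKN1A -0.178 to 0.125. Except where a reason is given, the cause was not tested.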

Other observations

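The 4 lists in this and the next paragraph, the FAM86 family, the deletion test and the cycling-cell test were chosen only after the results were seen. Set test p values of these 4 lists come from the same data that led to the choice, so they are no independent support. Of 10 tested targets of the aryl hydrocarbon receptor 4 rose with carnosine and 3 lay below 0. CYP1B1, a monooxygenase, rose by 1.66 ± 0.11 on the log2 scale (SE, adjusted p = 0.00417, edgeR), TIPARP by 1.07, NFE2L2 by 1.07 and AHRR by 0.93. Adjusted over the list alone 5 rose and 0 fell, and the median was 0.77. NQO1, at -0.27 ± 0.28 (adjusted p = 0.598), did not pass. CYP1A1, at 1.11 ± 0.58 (adjusted p = 0.269), did not pass either, with only 7 and 8 counts in the controls and 15 and 13 with carnosine. Camera gave a p of 0.0043 adjusted over these 4 lists alone, and an adjusted p of 0.17 with an estimated correlation. All 16 circadian clock and output genes lay above 0, with a median of 0.35. PER1 rose by 1.14, NR1D1 by 0.96, TEF by 0.72, BHLHE40 by 0.70 and NR1D2 by 0.56, 8 rose adjusted over the list alone, and camera gave a p of 9.08e-06 adjusted over the same 4 lists, and an adjusted p of 0.17 with an estimated correlation. BHLHE40 was not called without control replicate 1 (adjusted p = 0.0679) or 2 (0.0826), nor NR1D2 without control replicate 1 (0.132), control replicate 2 (0.0946) or carnosine replicate 2 (0.0521).

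Of 16 polyamine genes ARG2, AZIN2 (0.89) and AMD1 (0.77) rose and SAT1 fell, with 3 up and 3 down adjusted over the list alone, and ODC1, at -0.61, did not pass (adjusted p = 0.0839). The median of that list was -0.19, its mean 0.01 and its camera direction down (adjusted p = 0.591). Among 19 receptor tyrosine kinases and ligands, PDGFRA, PDGFRB, CSF1 (1.03), EPHA4 (0.84) and VEGFA rose and ERBB2 (-1.54), CSF1R and HBEGF (-0.74) fell, with 5 up and 4 down adjusted over the list alone (camera adjusted p = 0.591). AZIN2, AMD1 and VEGFA were not called without control replicate 1 (adjusted p = 0.0966, 0.0602 and 0.113) or 2 (0.0705, 0.0538 and 0.0826), AZIN2 also not without carnosine replicate 1 (0.0525). EPHA4 was not called without control replicate 1 (0.0961), nor HBEGF without control replicate 2 (0.0983) or carnosine replicate 1 (0.058). EEF2KMT, a lysine methyltransferase, fell by 1.13 ± 0.13, and its relatives FAM86B1, FAM86B3P, FAM86C1, FAM86C2P, FAM86DP, FAM86EP and FAM86JP fell by 1.51, 1.29, 1.10, 1.36, 0.53, 1.15 and 1.92. FAM86B2, FAM86FP and FAM86HP did not pass, and reads of such similar copies can be shared. FAM86B1 (0.0623), FAM86B3P (0.0736) and FAM86DP (0.122) were not called without control replicate 1, nor FAM86DP (0.0761) and FAM86EP (0.0571) without control replicate 2.

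In a block of chromosome 6 (28903002 to 33457548, GRCh38) 169 of 176 protein-coding genes had a mean count under 100, with 0 counts of RPS18, TUBB and TAP1 in all 4 libraries, and in a block of chromosome 16 (14435701 to 16393954) 17 of 23 did. A deletion would leave few expressed genes, yet 6 genes of the chromosome 6 block had at least 100 counts in every library, such as HLA-DRB1 with 7711 to 13128. Loss of reads that also align to alternate copies of these regions may explain the low counts, since 163 of the 176 genes are also listed outside the primary assembly. Listing and counts part for some genes of the block. VARS2 and C6orf48 are not listed outside the primary assembly and had a mean count of 0. HLA-DRB1, HLA-DQB1 and PRRC2A are listed there, with mean counts of 9926.75, 2278.75 and 366.5. The listing goes by gene symbol, and VARS2 and C6orf48 lie between listed genes. It does not show which reads have several matches, so these genes do not decide the question. Outside the blocks, genes were compared in families picked by name as used by every cell. Of those also listed outside the primary assembly, 33.3% (7 of 21) had a mean count under 100, against 11 of 364 others (Fisher's exact test, two-sided, p = 1.09e-05). The other 14 of the 21 had counts of 100 or more. Members such as DDX4, DDX25 and PSMB11 had almost no counts without such a listing, so a low count need not mean lost reads. These families were picked after the blocks had been seen, and no alignments were at hand to test the explanation directly.

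Sense-intronic transcripts, which lie within introns of other genes on the same strand, had a median log2 fold change of 0.39 over 221 genes, 168 of them above 0, though 4 were called higher and 1 lower, and other classes also lay above 0 (genes of unsettled type, TEC, 0.43 over 238 genes, 12 called higher and 3 lower; sense-overlapping 0.34 over 60, 3 higher and 0 lower). Higher expression of the host genes could give this, but the median difference from 209 tested hosts was 0.34 and the hosts' own median 0.08. Low counts were tested with protein-coding genes matched on expression, and 0 of 10000 draws reached 0.39, with a highest of 0.35. The median of the draws was 0.13, so matched genes also lay above 0. Genes were drawn independently, so a shift shared by these transcripts is outside the spread of the draws. Sense-intronic, sense-overlapping and TEC genes together took 0.0586% and 0.0586% of the counts in controls and 0.0852% and 0.0694% with carnosine, and the nuclear RNAs MALAT1 and NEAT1 0.166% and 0.143% against 0.427% and 0.329%. A larger share of unspliced or nuclear RNA, from carnosine or from the extraction, may lie behind both, but these shares are part of the pattern and do not test it. Other noncoding classes did not move together. Medians were 0.03 for 850 lincRNA, 0.03 for 928 antisense and -0.27 for 20 snRNA genes, but 0.24 for 46 snoRNA and 0.31 for 42 misc_RNA genes. The list named for nuclear long noncoding RNAs had a median of 0, with 7 members above 0 and 5 below. It also holds hosts of small nucleolar RNAs, among them SNHG15 and SNHG5, the 2 members called lower. Its median therefore does not measure nuclear RNAs alone.

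The fall of DNA replication genes was tested against trends of the fold changes with GC content, length and expression, and the median was -0.52 after their removal (22 of 22 genes below 0). A lower share of cycling cells could lower these genes together with mitosis genes. The replication minus mitosis difference lay between -0.54 and -0.21 over the 4 pairs of a carnosine and a control library, while replicates differed by up to 0.27, so the cycling share is left open.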
